A study of Rattus norvegicus with 54 samples.

How the data were processed

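Small RNA libraries were made from Sprague Dawley rat hippocampal neurons taken at embryonic day 18.5, cultured and transduced with lentivirus on day 9 in vitro, per the labels. RNA was extracted with Trizol, libraries were built with the TruSeq small RNA kit, and tagged Ago2 was pulled down with anti-FLAG beads. The submitters' processing notes name Bowtie 0.9.9.1 and the rat genome build rn4. The counting rule, the miRNA annotation version, the adapter trimming and any filter on read length are not given in the sources used here.

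The authors deposited 1 table of 728 mature miRNAs by 54 libraries. Its values are in log2 units: the lowest is 3, and after the offset of 8 is removed the libraries of an experiment sum to 1 total, so the deposited unit is log2 of normalised reads plus 8. The totals lay between 5489059 and 5489156 for the 18 Syn-Target libraries and between 11551514 and 11551698 for the 36 time-course libraries, so no comparison was made across these experiments. The values were taken back to normalised reads. Low values fell on steps of 1 scaled read, and 78.4% to 92.4% of them were whole reads within a tolerance of 0.1, which left fractions that rule out a count model. Depth was estimated as the total divided by the value of 1 read, and ranged from 2294112 to 19013944 reads. It counts reads given to listed miRNAs only. No coordinates are given, because the table holds none.

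Differences were tested with limma 3.58.1 in R 4.3.3 on log2(normalised reads + 1), for miRNAs with a mean of at least 10 over the libraries of the fit, without a trend and without robust weights. The Benjamini-Hochberg adjusted p had to be under 0.05, and all tests were two-sided. All 18 Syn-Target libraries entered 1 fit with a mean per group, so its error comes from the spread within groups of 2 libraries and not from that among groups. WT was compared with mut for each target, the Ext effect was compared with the Seed effect, and the 4 mut groups were compared with the non-infected group. The 36 time-course libraries gave slopes of WT over mut per log2(hours + 1) with a term per time point, within each of the 3 series, averaged over them, and as IP minus input, and a slope on time within the mut target. IP and input, and input and total RNA, were compared as 12 pairs that share construct and time. Replicate numbers were not treated as pairs: the correlation of deviations between libraries with like numbers was over 0.1 in 28 of 36 pairs of groups and under -0.1 in 2, but was 0.02 for the Ext miR-132 pair. Single ratios over time were tested by exact permutation over pairings, and the miR-132-3p and miR-124-3p levels by exact permutation over libraries, with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

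There were 11 lists: miR-124 arms, miR-132/miR-212 arms, neuron-enriched, the miR-379/410 cluster, the let-7 family, miR-17-92 and its paralogs, astrocyte-enriched, oligodendrocyte-enriched, microglia and blood, endothelial, and inflammation-responsive. A list of minor arms was computed from the table as the lower arm of each of 265 arm pairs. Of 105 listed names, 12 had no match, and the endothelial list matched 0 miRNAs and was not tested. Names were matched by family number and arm, so miR-9, miR-218 and miR-219, which the table names 9a, 218a and 219a, were not matched from the lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of the 8 list calls at the preset correlation, 0 held with an estimated correlation. fry, which tests whether a list moves one way without comparing it with other miRNAs, called 5 lists in transduced cells (miR-17-92 at an adjusted p of 0.0038, and the miR-379/410 cluster, miR-132/miR-212 arms, neuron-enriched and inflammation-responsive lists each at 0.0326), 1 for Ext miR-132 WT against mut, 7 for the slopes in total RNA, 10 for IP against input, 5 for input against total RNA and 0 in the other comparisons. Under no filter, a mean of at least 100 or median-of-ratios rescaling, 13 camera results crossed the threshold.

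The lists, comparisons, tests, alternatives and the rule for which miRNAs the text names were fixed before the data were examined. The rule takes every arm of miR-124, miR-132 and miR-212, the 10 largest increases and the 10 largest decreases among calls whose groups do not overlap or whose pairs all go one way (slopes have no such condition), and up to 4 of the most abundant members of each list. miRNAs named outside the rule are members of a list or are said to be chosen after their values were seen. The methods were tested on simulated data with 60 changed miRNAs. In the comparisons of WT with mut, a change of 2 on the log2 scale was called in 90% to 100% of cases and a change of 1 in 55% to 65%, and in the comparison with non-infected cells in 95% and 70%. A slope of 0.4 was called in 90% of cases in total RNA, 100% in the input, 90% in the IP and 50% for IP minus input. Unchanged miRNAs that were called numbered 0 to 5 per comparison. A list shifted by 0.5 was called (camera adjusted p = 2.04e-12) and 0 of 10 other lists were. The simulated noise was independent between miRNAs, so this does not test list calls where members move together. With 60 changed miRNAs the Benjamini-Hochberg cut-off is also looser than for a change that stands alone. The shares called are therefore likely too high for comparisons with few changes.

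Alternatives were a pseudocount of 0.5 or 8, no filter, a mean of at least 100, median-of-ratios rescaling, rescaling to a total without the targeted arms, a trend with robust weights, the replicate number as a block, each replicate or time point left out, only the compared groups in the fit, other control groups, linear hours, a step at 24 hr, no term per time point and no pairing. Added after seeing the data were fits without the total mut 72 hr library and without 3 libraries that stand apart from their series (total mut 72 hr, Ago2 input WT 4 hr and Ago2 IP WT 2 hr), and the comparison of Ext with Seed constructs. No library was left out of the values reported first. Read lengths, added 3' bases and messenger RNA were not analysed here.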

Results

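Small RNA was sequenced from 54 libraries of primary hippocampal neurons prepared from rat embryos and transduced with lentiviral vectors that carry sites for a neuronal microRNA (miRNA). In the Syn-Target experiment, 18 libraries formed 9 groups of 2. Of these groups, 8 carried a target driven by the Synapsin promoter, named in the labels as Ext or Seed, by its miRNA (miR-124 or miR-132) and by its version (WT or mut), and the other group was not infected. The labels do not spell out Ext, Seed, WT or mut, and the words are used here as names only. In the time-course experiment, a miR-132 target under doxycycline control was sampled at 0, 2, 4, 8, 24 and 72 hr in its WT and mut versions. Each of these 12 conditions was sequenced in total RNA, in the input of cells that also carried tagged Ago2 (an Argonaute protein, which holds mature miRNAs), and in the Ago2 immunoprecipitate (IP). The time course had 1 library per condition, and the labels do not say whether the paired Syn-Target libraries come from separate cultures, so their spread may be technical. Values are normalised reads, taken back from the deposited log2 scale. Estimated depth was 2294112 to 13351226 reads per library in the Syn-Target experiment, 6431659 to 19013944 in the total RNA series, 8261198 to 17169024 in the Ago2 input and 9300996 to 11217012 in the IP. Between 503 and 620.0 of the 728 listed miRNAs had a value above 0 in a library, and the 10 most abundant miRNAs took 55.1% to 63.1% of the reads. Values near 1 normalised read rest on about 1 read and are imprecise.

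The first question was whether a miR-132 target changes the level of the miRNA it binds. With the Ext miR-132 WT target, miR-132-3p, an activity-responsive neuronal miRNA, stood at 1584 and 1958 normalised reads, against 14652 and 16975 with the mut target. The other 14 libraries, non-infected cells included, lay between 10725 and 17704. The fall was 8.95-fold (log2 change -3.16, SE 0.17, 95% interval -3.54 to -2.79, limma adjusted p = 1.1e-07, n = 2 against 2), and both WT libraries lay below all 16 others (exact permutation test, two-sided, p = 0.0131, the smallest that 153 splits allow). The permutation takes all libraries as independent. They come in groups of 2 whose spread may be technical, so its p may be too small. The opposite arm of the same precursor, miR-132-5p, did not follow: it stood at 1250 and 1375 normalised reads with WT and at 785 and 1403 with mut (log2 change 0.32, SE 0.27, interval -0.26 to 0.90). The arms of miR-212, which shares the miR-132 transcript and seed, gave 0.23 for miR-212-3p and 0.30 for miR-212-5p, each with an adjusted p of 0.998. With the Seed miR-132 WT target, miR-132-3p differed from mut by 0.16 (SE 0.17, interval -0.21 to 0.54), so a loss of the size seen with Ext lay outside its interval.

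Among 429 miRNAs tested with limma, miR-132-3p was the 1 that passed for the Ext miR-132 target, where 6 had an unadjusted p under 0.05. For the Seed miR-132 target 0 passed in limma and 4 had an unadjusted p under 0.05. The difference between the Ext and Seed effects was itself tested, and miR-132-3p was the 1 miRNA past the threshold (-3.32, SE 0.25, adjusted p = 3.67e-06, against 4 at an unadjusted p under 0.05). In that difference the list of miR-132/miR-212 arms was called lower as a set (camera adjusted p = 0.0028, which became an adjusted p of 0.54 with an estimated correlation). The call rested on miR-132-3p, since the median of the 4 arms was 0.04. Leaving out replicate 1 of Ext miR-132 WT added miR-299a-5p to the calls of the Ext comparison, and leaving out replicate 2 of Ext miR-132 mut added miR-17-1-3p, so that 2 miRNAs passed in each of those fits. Both were named after their values were seen.

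**Figure D1:**
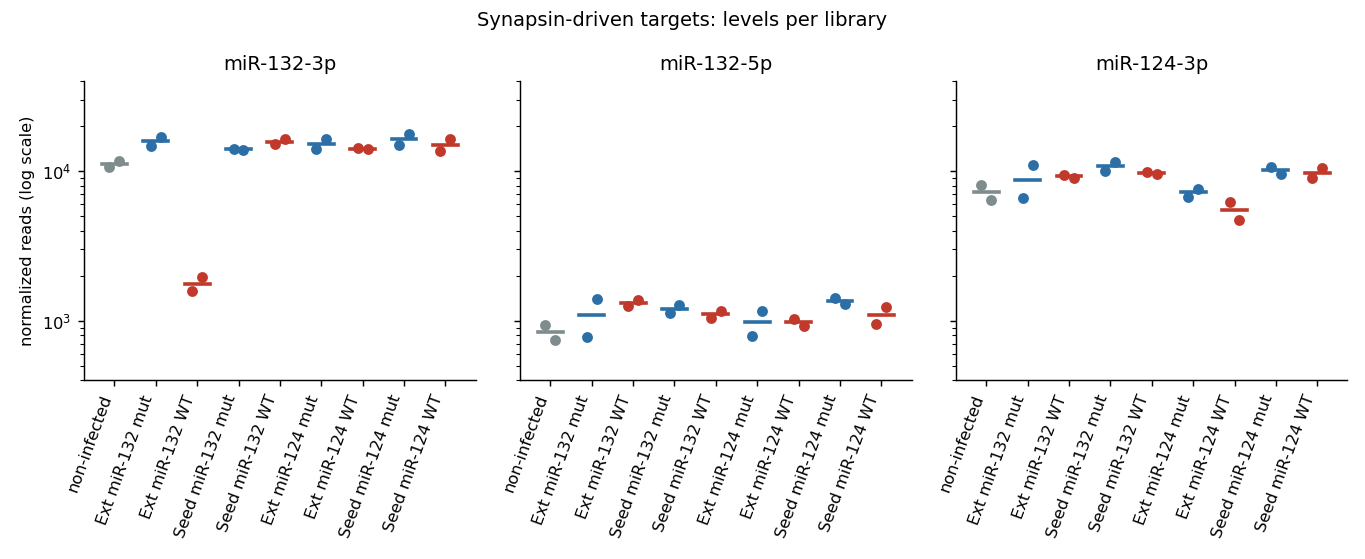
Normalised reads (log axis) of miR-132-3p, miR-132-5p and miR-124-3p in each of the 18 Syn-Target libraries, by group, with 1 point per library. The 2 points of miR-132-3p with the Ext miR-132 WT target lie at 1584 and 1958, below all other libraries.

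The same design was applied to miR-124, an abundant miRNA of neurons. With the Ext miR-124 WT target, miR-124-3p stood at 6237 and 4694 normalised reads, against 6770.3 and 7642 with the mut target and 8056 and 6455 in non-infected cells. The difference from mut was -0.41 (SE 0.23, interval -0.92 to 0.10, limma adjusted p = 0.83) and did not pass the test. With the Seed miR-124 WT target the difference was -0.06 (interval -0.56 to 0.45). The passenger arm miR-124-5p gave -0.13 with Ext and -0.16 with Seed, and neither passed. Set against all 16 other libraries, the Ext miR-124 WT pair was the lowest of 153 splits (log2 difference -0.73, exact permutation p = 0.0131). That comparison mixes constructs and takes the 2 libraries of a group as independent, so its p may be too small. The difference between the Ext and Seed effects on miR-124-3p was -0.35 (SE 0.33), which also did not pass.

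Over all 429 miRNAs, limma called 0 for the Ext miR-124 target (26 at an unadjusted p under 0.05), 0 for the Seed miR-124 target (7) and 0 for the difference between them (9). Without replicate 2 of Ext miR-124 mut, miR-187-5p was called both for Ext and for the difference. With all groups that lack a WT miR-124 target as the control, miR-221-5p, miR-409a-5p and miR-410-5p were called for Ext. These 4 were named after their values were seen. In the 4 comparisons of WT with mut in this experiment camera called none of the fixed lists, while fry called the miR-132/miR-212 arms for Ext miR-132 (adjusted p = 0.0181) and no other list. With a mean of at least 100 camera called the astrocyte-enriched list lower for Seed miR-132 (adjusted p = 0.0449, against 0.213 with the filter used first and 0.964 there with an estimated correlation). For the difference between Ext and Seed of miR-124, median-of-ratios rescaling added calls of let-7 lower (adjusted p = 0.0401) and of minor arms higher (adjusted p = 0.0498), and both had an adjusted p of 0.741 with an estimated correlation on the deposited scaling.

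Carrying a vector at all was compared with carrying none, using the 8 libraries with mut targets against the 2 non-infected ones. The largest increases were in miR-10a-5p and miR-10b-5p, which lie in Hox gene clusters: miR-10a-5p went from 6.36 ± 5.81 (SD, n = 2) normalised reads to 362 ± 164 (SD, n = 8), and miR-10b-5p from 14.3 ± 0.448 to 276 ± 139. In log2 these were 5.75 (SE 0.61) and 4.02 (SE 0.53). The non-infected values of miR-10a-5p are 2 and 6 reads, and its change was 4.84 without non-infected replicate 1 and 6.66 without replicate 2. Both miRNAs were higher in replicate 1 than in replicate 2 in all 8 transduced groups. miR-21-5p, which is induced in stressed and inflamed tissue, rose 2.23-fold (14197 ± 2589 to 31799 ± 5708). The largest decreases were in miR-219a-2-3p, an oligodendrocyte-lineage miRNA (678 ± 362 to 34.8 ± 7.80, 17.9-fold lower), and in arms of miR-322, miR-351, miR-450a, miR-503 and miR-542. All 7 tested arms of these 5 were called lower; they formed no fixed list and were not tested as a set. Of them miR-322-5p fell 8.94-fold (4097 ± 712 to 522 ± 298), miR-542-3p 7.66-fold (2712 ± 65.7 to 369 ± 123), miR-351-5p 7.46-fold (36676 ± 2201 to 5062 ± 1290) and miR-450a-5p 6.44-fold (2245 ± 802 to 355 ± 126). miR-881-3p also rose, but stood at 2.2 and 0 in the non-infected libraries, which is 2 reads and 0.

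By group, 8 of the 16 tested members of the proliferation-associated miR-17-92 clusters fell (14 when adjusted over the list alone), among them miR-92a-3p (-1.53, SE 0.25) and miR-93-5p (-0.81, SE 0.15), and the list's median was -0.85 (camera adjusted p = 6.5e-12, adjusted p = 0.10 with an estimated correlation). Of the imprinted miR-379/410 cluster, 2 of 47 rose (0 adjusted over the list alone, median 0.34, adjusted p = 8.07e-06, and adjusted p = 0.41 with an estimated correlation). The neuron-enriched list (1 of 27 higher, 0 adjusted over the list alone, median 0.25), the miR-132/miR-212 arms (0 of 4 called, 2 adjusted over the list alone, median 0.44) and the inflammation-responsive list (1 of 8 higher, 2 adjusted over the list alone, median 0.41) were each called higher at an adjusted p of 0.045, and each had an adjusted p of 0.41 with an estimated correlation. The neuron-enriched and miR-132/miR-212 calls were lost at a mean of at least 100 (adjusted p = 0.0554 for both), and the inflammation-responsive call without a filter (adjusted p = 0.122). miR-132-3p itself was at 0.45 (adjusted p = 0.074). Of lists for other cell types, astrocyte-enriched miRNAs had 1 higher and 1 lower of 18 (also when adjusted over the list alone), oligodendrocyte-enriched 0 of 5, and microglia and blood 0 of 4. The oligodendrocyte list did not hold miR-219a-2-3p, whose name in the table differs from the listed one. Its miR-138 arms are also on the neuron-enriched list, which leaves only the arms of miR-338, so it says little about that cell type. The let-7 family had 0 of 19 called, with a median of -0.05 (adjusted p = 0.054), and became a call for lower after median-of-ratios rescaling (adjusted p = 0.028) and without a filter (adjusted p = 0.0324, and 0.61 with an estimated correlation on the deposited scaling). Of 135 tested minor arms, 3 were higher and 6 lower, with a median of 0.04 and a mean of -0.02.

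In all, limma called 33 of 429 miRNAs, 10 higher and 23 lower. The groups did not overlap for any of the 33, but miRNAs that pass limma tend to have groups that lie apart, so this is no further support. For a miRNA not picked by its result, chance alone keeps 8 and 2 independent libraries apart in 4.44% of cases. After median-of-ratios rescaling there were 35 calls, 7 higher and 28 lower, so the share of higher calls was 20% in place of 30.3%, and 28 of the 33 remained. With the replicate number as a block there were 56 calls, 26 higher and 30 lower (46.4% higher), which held all 33. Only 2 libraries stand for non-infected cells: without replicate 1 of them 21 miRNAs were called, and without replicate 2, 12. Without replicate 2, miR-21-5p was at 0.97 (adjusted p = 0.153), miR-92a-3p at -1.36 (adjusted p = 0.0602) and miR-93-5p at -0.78 (adjusted p = 0.076), and miR-132-3p was called in 3 of 19 alternatives: without replicate 1 of Ext miR-132 mut (0.47, adjusted p = 0.048), with the replicate block (adjusted p = 0.0169) and with trend and robust weights (adjusted p = 0.0408).

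**Figure D2:**
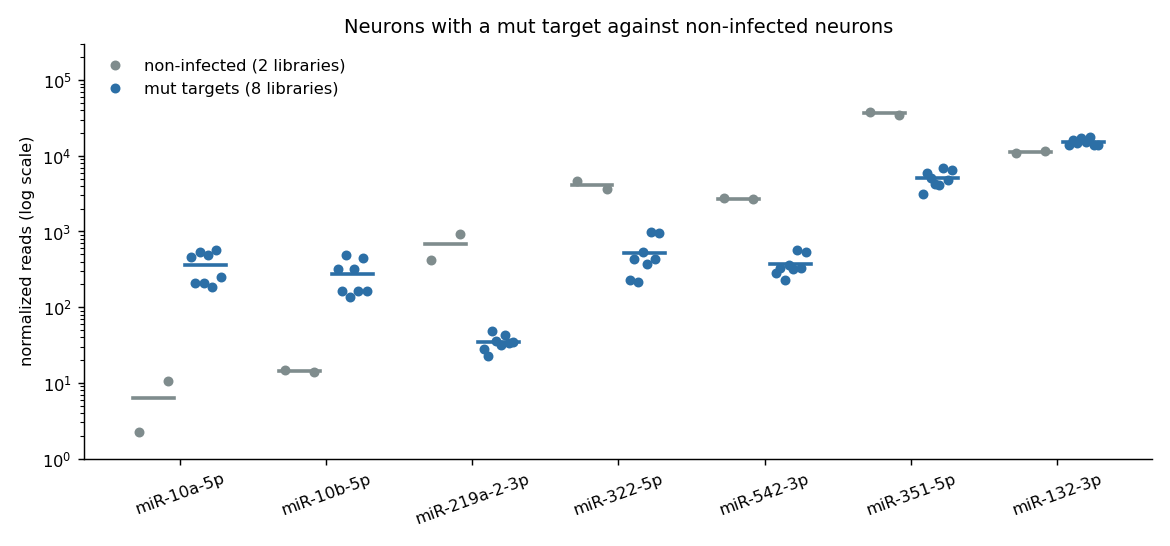
Normalised reads (log axis) of miRNAs that differed between non-infected cells (2 libraries) and cells with mut targets (8 libraries), with 1 point per library. miR-10a-5p averaged 6.36 in non-infected cells and 362 with mut targets, and miR-322-5p averaged 4097 and 522.

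The time course asked how fast the miRNA changes once target expression is switched on. In total RNA, miR-132-3p with the WT target stood at 88.9% of its level with the mut target at 0 hr, 73.5% at 2 hr, 96.2% at 4 hr, 74.3% at 8 hr, 40.3% at 24 hr and 11.2% at 72 hr (11722 against 104344 normalised reads). In the Ago2 input the share went from 62.2% at 0 hr, 70.04% at 2 hr and 62.9% at 4 hr to 45.1% at 8 hr, 29.8% at 24 hr and 11% at 72 hr. In the Ago2 IP it went from 60.5% at 0 hr and 81.4% at 2 hr to 34.0% at 4 hr, 29.4% at 8 hr, 18.2% at 24 hr and 6.99% at 72 hr (12860.0 against 183999). The passenger arm miR-132-5p stayed between 84.7% and 101% in the input and between 91.4% and 111% in the IP. In total RNA it lay between 80.9% and 109% up to 24 hr and at 223% at 72 hr, where the mut library held 3353 normalised reads against 6889 to 7896 in the other mut libraries. miR-212-3p ranged from 59.2% to 86.0% in the IP, lowest at 72 hr, from 84.6% to 106% in the input and from 76.0% to 108% in total RNA. miR-212-5p ranged from 88.8% to 105% in the IP, from 95.1% to 116% in the input and from 108% to 172% in total RNA, where it stood at 161% at 0 hr and lowest at 72 hr. miR-124-3p, which the target does not carry sites for by its label, stayed between 75.1% and 130% in the 3 series.

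Across the 6 time points, the log2 ratio of WT to mut fell with hours in each series by Pearson's r (total -0.99, exact permutation p = 0.0222; input -0.98, p = 0.0111; IP -0.92, p = 0.00833; adjusted over the family of 3, 0.0222, 0.0167 and 0.0167). Spearman's rho was -0.71 in total RNA (exact permutation p = 0.136, adjusted 0.136), -0.83 in the input (p = 0.0583, adjusted 0.0875) and -0.94 in the IP (p = 0.0167, adjusted 0.05). Without the 24 and 72 hr points r was -0.35 in total RNA, -0.83 in the input and -0.81 in the IP, and rho was 0, -0.4 and -0.8, so the relation in total RNA rests on those points and that in the input does so by rank.

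In limma, the slope of WT over mut per log2(hours + 1), averaged over the 3 series, called 2 of 484 miRNAs: miR-132-3p (-0.47, SE 0.06, adjusted p = 6.5e-04) and miR-1193-3p (0.10, SE 0.02, adjusted p = 0.047), with 81 at an unadjusted p under 0.05. The input and IP come from the same cells but entered as independent series, so the SE and p of this average may be too small. Without the 72 hr points miR-132-3p was at -0.30 (adjusted p = 0.071), and without any 1 of the time points miR-1193-3p was not called. Leaving out the total mut 72 hr library, a choice made after seeing the data that also takes its WT partner out of the slope, 3 were called, miR-132-3p with miR-210-3p and miR-222-5p, and without 3 libraries that stand apart from their series 4 were called. Within series, the slope of miR-132-3p was -0.46 in total RNA (SE 0.10, adjusted p = 0.022), -0.41 in the input (adjusted p = 0.37) and -0.54 in the IP (adjusted p = 0.062, called in 8 of 18 alternatives, among them the fits without the 0 hr points and without the total mut 72 hr library). The IP slope minus the input slope was -0.12 (SE 0.15, interval -0.44 to 0.19), so a faster loss in the IP was not shown.

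For other miRNAs, limma called 0 slopes in the input (10 at an unadjusted p under 0.05), 0 in the IP (15) and 0 in the difference between them (3). In the IP camera called the miR-132/miR-212 arms lower as a list (adjusted p = 0.013), and microglia and blood miRNAs higher (adjusted p = 0.034), both with an adjusted p of 0.21 with an estimated correlation. The list of arms holds the targeted miR-132-3p and was not tested without it. Of its other arms in the IP, miR-212-3p was at 59.2% of mut at 72 hr. There miR-132-5p lay between 91.4% and 111% over all times, and miR-212-5p between 88.8% and 105%. The call of microglia and blood was lost without a filter (adjusted p = 0.158) and at a mean of at least 100 (adjusted p = 0.0569). The 5 tested microglia and blood members had a median slope of 0.06 and 0 calls, also when adjusted over the list alone. In total RNA 129 slopes passed, 115 higher and 14 lower, led by miR-509-5p (0.67) and miR-190a-3p (0.48) upward and by miR-132-3p and miR-10b-5p (-0.27) downward, and miR-132-5p was among them (0.22, SE 0.04, adjusted p = 0.017). Some single changes removed most of these calls. Without the total mut 72 hr library 2 passed, miR-210-3p and miR-222-5p, of which 1 was among the 129, and miR-132-3p was at -0.22 (adjusted p = 0.985). With 1 library per condition the WT library of 72 hr then drops out of the slope too. The slope in total RNA is then the one without the 72 hr points, and 1 library is not singled out. The input and IP keep their 72 hr points there, so the error and the calls can differ. Without the 0 hr points 69 passed, without the 8 hr points 1 (miR-450a-5p), and after median-of-ratios rescaling 3, of which 66.7% were higher in place of 89.1%. By list in total RNA, astrocyte-enriched miRNAs had 9 of 18 higher (10 adjusted over the list alone), the let-7 family 8 higher and 1 lower of 19 (12 and 2) and the miR-17-92 clusters 8 of 18 higher (8 higher and 1 lower), and none of the lists was called by camera, while fry called 7 of 11, minor arms included.

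**Figure D3:**
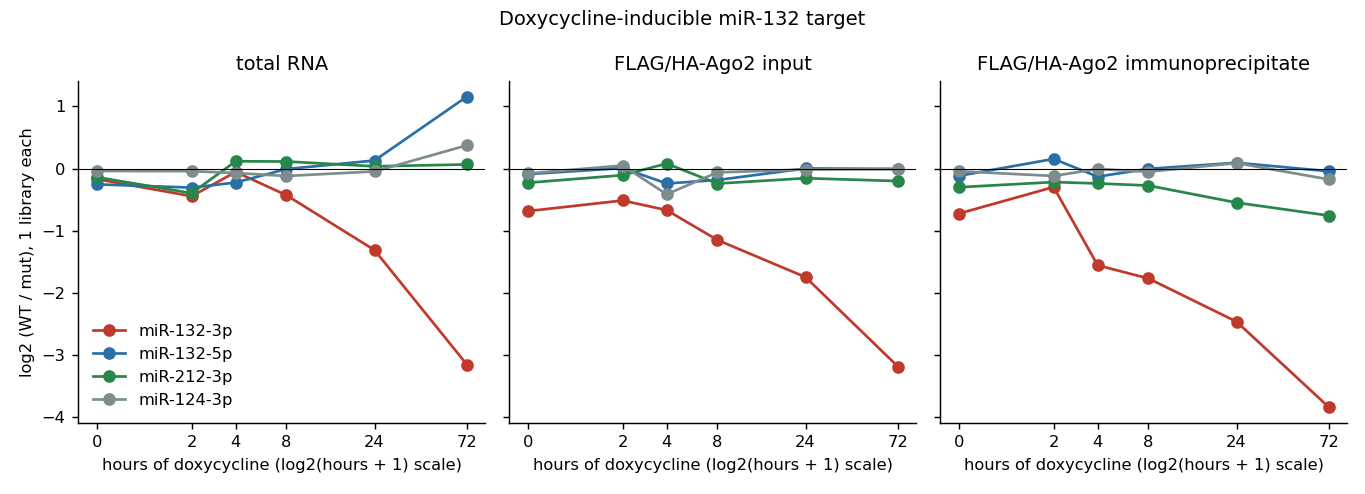
Log2 ratio of WT to mut for miR-132-3p, miR-132-5p, miR-212-3p and miR-124-3p, against hours of doxycycline on a log2(hours + 1) scale. The panels show total RNA, Ago2 input and Ago2 IP, with 1 library per point on each side. At 72 hr miR-132-3p lay at -3.15, -3.18 and -3.84 in the 3 series, which is 11.2%, 11% and 6.99% of mut.

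Hours of doxycycline were also compared within the libraries with the mut target, as a slope averaged over the 3 series. The SE and p of this slope may also be too small, since input and IP share cells but entered as independent. Among the largest increases with time were miR-743b-3p (0.25 per log2(hours + 1), SE 0.05, adjusted p = 0.0016), miR-463-5p (0.25), miR-743a-3p (0.24), miR-881-3p (0.21) miR-741-3p (0.21), miR-183-5p (0.21) and miR-182 (0.19). Among the decreases, miR-34c-5p fell by 0.20 (SE 0.04) and miR-34b-5p by 0.17 per unit. miR-132-3p was at 0.05 (adjusted p = 0.30). Among the lists, 5 of 18 astrocyte-enriched miRNAs fell and 1 rose (7 and 1 adjusted over the list alone), 4 of 19 let-7 members fell (4 adjusted over the list alone), and 1 of 10 inflammation-responsive miRNAs rose (3 higher and 1 lower adjusted over the list alone). Camera called none of the lists, and after median-of-ratios rescaling it called the miR-379/410 cluster higher (adjusted p = 0.0398, against 0.104 on the deposited scaling and 0.955 there with an estimated correlation).

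Limma called 86 of 484 slopes, 21 higher and 65 lower. After median-of-ratios rescaling there were 94, of which 53.2% were higher in place of 24.4%. Without the total mut 72 hr library 15 passed, without the 72 hr points 6, without the 2 hr points 55 and without the 24 hr points 142. Without that library miR-743a-3p, miR-183-5p (0.13, adjusted p = 0.136), miR-182 (0.13), miR-34c-5p (-0.10) and miR-34b-5p (-0.11) were not called, and without the 72 hr points miR-743b-3p, miR-881-3p, miR-741-3p, miR-183-5p (0.02), miR-182, miR-34c-5p (-0.06) and miR-34b-5p were not. miR-743a-3p was also not called without the 2 or the 8 hr points.

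The Ago2 IP was compared with its input to see which miRNAs the tagged protein held. Of let-7, let-7e-5p and let-7d-5p stood among the largest increases. let-7e-5p went from 17668 ± 1023 (SD, n = 12) normalised reads in the input to 105765 ± 11155 in the IP (log2 change 2.58, SE 0.05), and let-7d-5p rose by 2.09. Smaller rises were those of let-7f-5p (1.59), let-7a-5p (1.5) and let-7c-5p (1.16). miR-672-5p rose 9.34-fold (856 ± 55.5 to 8055 ± 1108), miR-3099 by 2.44 and miR-485-3p by 2.37, each in all 12 pairs. Of the largest decreases, miR-379-5p fell 19.2-fold (1102 ± 188 to 56.6 ± 10.1), miR-34c-3p 15.7-fold and miR-331-3p 11.02-fold (7376 ± 1173 to 663 ± 64.7), again in all 12 pairs. miR-124-3p fell by 1.15 on the log2 scale (25340.1 ± 2434 to 11364 ± 502.8) and miR-124-5p by 0.90. Both arms of miR-132 changed little on average, with 0.25 for miR-132-3p and 0.12 for miR-132-5p at an adjusted p of 0.04997. For miR-132-3p this average pools unlike pairs: IP over input was between 1.18 and 1.83 in the 6 mut pairs, but in the WT pairs it was 1.42 at 0 hr, 1.64 at 2 hr, 0.992 at 4 hr, 0.848 at 8 hr, 0.765 at 24 hr and 0.752 at 72 hr. Each call was lost in 8 of 15 alternatives. Both were lost without a filter, without pairing, without the 0, 2 or 4 hr points and without the 3 libraries that stand apart, that of miR-132-3p also with a pseudocount of 0.5 and with the total without targeted arms, and that of miR-132-5p also with a pseudocount of 8 and without the 24 hr points.

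Of the let-7 list, 8 of 19 members were higher and 11 lower, the latter led by let-7b-3p (-2.78), let-7a-2-3p (-2.48) and let-7f-1-3p (-1.94). The miR-17-92 clusters had 0 higher and 16 lower of 18 (median -1.35), astrocyte-enriched miRNAs 1 higher and 17 lower of 19, neuron-enriched miRNAs 7 higher and 16 lower of 27, the miR-379/410 cluster 11 and 27 of 49, oligodendrocyte-enriched miRNAs 1 and 3 of 5, microglia and blood 1 and 3 of 5, inflammation-responsive miRNAs 2 and 5 of 10, and the arms computed as minor 29 and 104 of 159. Adjusted over the list alone the counts were the same except for 28 minor arms higher. Camera, which compares a list with all other miRNAs, called none of them, while fry called 10 of 11. After median-of-ratios rescaling camera called the miR-17-92 clusters lower (adjusted p = 0.017), as it did without a filter (adjusted p = 0.0262), against 0.0976 before these changes and 0.828 there with an estimated correlation.

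Limma called 410 of 481 miRNAs, 99 higher and 311 lower, and 306 of the calls went one way in all 12 pairs. Chance gives this in 0.0488% of cases for a miRNA not picked by its result, while the 306 were counted among calls. The median of all miRNAs was -0.49, and this shift moves the direction of small changes. With median-of-ratios rescaling the median was -0.03 and 396 miRNAs were called, of which 48.5% were higher in place of 24.1%. Under that scaling miR-212-3p went from -0.30 to 0.17 and miR-212-5p from -0.20 to 0.27, while miR-124-3p stayed lower (-0.68) and miR-132-3p was at 0.72.

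**Figure D4:**
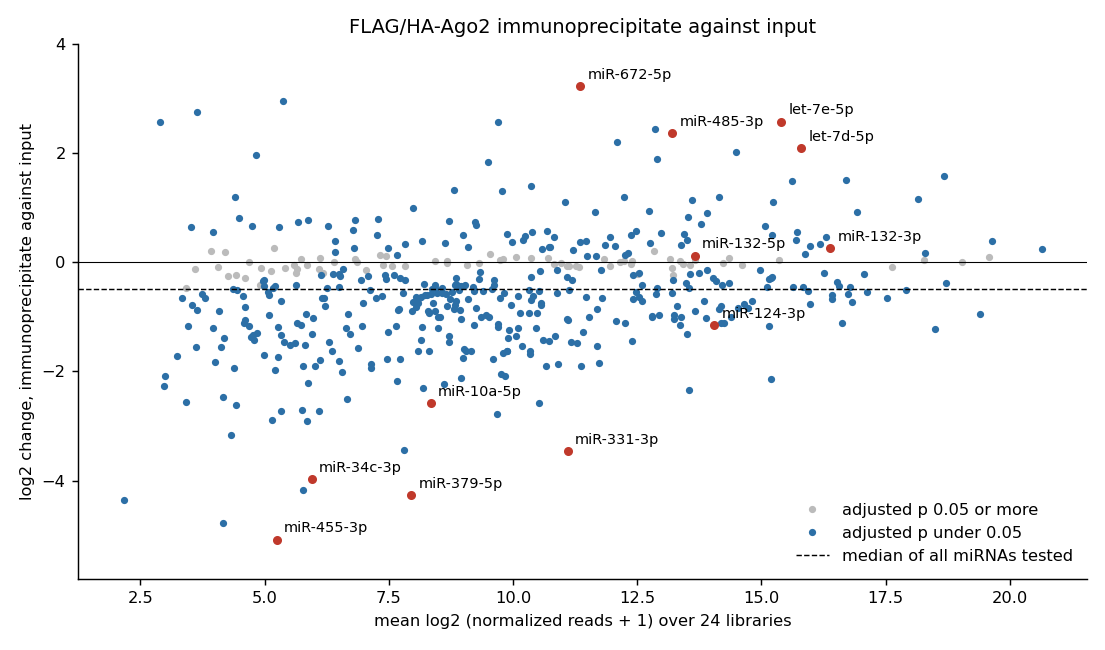
Log2 change of each tested miRNA between the Ago2 IP and its input against its mean log2 level, with named miRNAs marked. The median of all 481 tested miRNAs lies at -0.49, with miR-672-5p at 3.22 and miR-379-5p at -4.26.

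The last comparison set the Ago2 input against total RNA from the cells without tagged Ago2. The 2 series are separate experiments, so the added Ago2 and the experiment cannot be told apart. miR-543-3p stood at 1558 ± 123.9 (SD, n = 12) in total RNA and 8867 ± 523 in the input (log2 change 2.51, SE 0.06), miR-222-3p rose by 2.34 (5987 ± 777 to 30272 ± 3492), miR-128-3p by 1.54 and miR-21-5p by 1.19. The hypoxia-responsive miR-210-3p fell 7.78-fold (2922 ± 1218 to 348 ± 33.7). Also lower were miR-322-5p at -2.75 (7357 ± 1644 to 1083 ± 168), miR-542-3p at -2.44, miR-351-5p at -1.93 and miR-146a-5p at -1.57. All 4 arms of miR-132 and miR-212 were higher (miR-132-5p 0.93, miR-212-5p 0.59, miR-132-3p 0.54, miR-212-3p 0.38), and both arms of miR-124 were lower (miR-124-3p -0.40, miR-124-5p -0.53).

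By list, the miR-379/410 cluster had 27 of 50 higher and 10 lower, neuron-enriched miRNAs 11 and 6 of 27, let-7 8 and 9 of 19, astrocyte-enriched 8 and 3 of 20, inflammation-responsive 5 and 2 of 10, and the miR-17-92 clusters 4 and 6 of 19 (3 and 6 adjusted over the list alone, where the others kept their counts). Camera called none of the lists, and fry 5 of 11. Limma called 357 of 492 miRNAs, 207 higher and 150 lower, of which 218 went one way in all 12 pairs, and the median of all was 0.11.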

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

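Of the tests in this part, those on library scaling and on the precursor were chosen only after the result was seen.

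The effect of the WT target on miR-132-3p differed between the Ext and Seed constructs by -3.32 on the log2 scale (SE 0.25, limma adjusted p = 3.67e-06), and this difference between groups is what marked it for a closer look. It kept its direction and its call in all 17 alternatives, between -3.48 and -3.17, with adjusted p from 3.27e-07 to 0.0032.

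The fall of miR-132-3p with the Ext WT target came without a fall of its passenger arm. Scaling of the libraries is argued against, since the ratio of miR-132-3p to miR-132-5p within a library, which scaling cannot move, differed between WT and mut by -3.48 (SE 0.23). Less transcription or processing of the precursor is argued against as the whole cause, since miR-132-5p was at 0.32 with an interval of -0.26 to 0.90, wholly above the change of miR-132-3p. Reads of miR-132-3p with tailed or trimmed ends that were not counted stay open, because the table has 0 columns by read length or added bases. Loss of the mature strand in cells with the Ext WT target, a biological reading that was not tested, may account for the fall and is a hypothesis here, since counted and uncounted strands cannot be told apart without values by read length.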

How the results depend on the processing

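Of the alternatives, those without the total mut 72 hr library, without the 3 libraries that stand apart and all for Ext against Seed constructs were chosen after seeing the data; the cause of each change below was not tested unless it is stated. Of 12041 alternative values for 735 results, 11263 kept their direction and side of the threshold or stayed within the limit for counts, 592 lost a call, 108 gained one, 59 counts moved and 19 reversed. miR-132-3p with the Ext WT target kept its call in all 14 alternatives (-3.32 to -3.01, adjusted p from 6.27e-09 to 0.0262). A left-out replicate leaves its group with 1 library, which is assumed to vary like the others. Depth limits the miRNAs near 10 normalised reads, where the filter acts.

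In the Syn-Target experiment, control groups without a WT miR-124 target, which mix Ext, Seed and non-infected cells, gave 3 calls for Ext miR-124. With each library left out, calls ranged from 0 to 1 for Ext miR-124, 0 to 1 for Ext minus Seed of miR-124, 1 to 2 for Ext miR-132, 12 to 44 for mut against non-infected, and for Ext against Seed (4.43% of tested miRNAs called) from 2.56% to 29.0%. The replicate block gave 56 calls for mut against non-infected and 7.46% for Ext against Seed. With mut groups only, Ext against Seed gave 1.63% and miR-132-3p was at 0.032, since no WT miR-132 target is then in it. The 8 list calls became 0 with an estimated correlation and 13 on median-of-ratios values.

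For the slopes in total RNA (129 calls), calls numbered 20 without a filter, 3 after median-of-ratios rescaling, 255 with linear hours and 0 with a step at 24 hr. Without the total mut 72 hr library there were 2. Its WT partner then drops out too, so the slope in total RNA is the one without the 72 hr points, though the error differs. Calls numbered 4 without the 3 libraries and 1 to 169 with each time point left out. There miR-132-3p was at -0.55 after rescaling (adjusted p = 0.0501), -1.96 with the step, -0.22 without the total mut 72 hr library and -0.22 without the 3 libraries, and -0.62 to -0.22 with time points left out. In that series let-7i-5p was at -0.0011 after rescaling, let-7b-5p at 0.0030 and miR-29a-3p at -0.0033 without the total mut 72 hr library and at those values also without the 3 libraries, and with time points left out let-7b-5p ranged from -0.28 to 0.0030 and miR-29a-3p from -0.0033 to 0.38.

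In the Ago2 input (0 calls) linear hours gave 1 call, miR-132-3p at -0.036 per hour. In the Ago2 IP (0 calls) 1 call, miR-132-3p, was gained with a pseudocount of 8 (-0.54), a mean of at least 100 (-0.54), trend and robust (-0.54), no term per time point (-0.54), the total mut 72 hr library left out (-0.54), the 3 libraries left out (-0.48) and linear hours (-0.042 per hour), and calls ranged from 0 to 1 with time points left out (miR-132-3p -0.68 to -0.43). The averaged slope (2 calls) gave 1 call with a pseudocount of 8, no filter, median-of-ratios rescaling, the total without targeted arms, trend and robust, and the step, 99 with linear hours, 3 without the total mut 72 hr library, 4 without the 3 libraries, and 0 to 1 with time points left out (miR-132-3p -0.63 to -0.30).

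For doxycycline time in mut (86 calls), linear hours gave 213, the step 51, the fit without the total mut 72 hr library 15 and that without the 3 libraries 46, and time points left out 6 to 142; miR-434-3p reversed to 0.046 without the 3 libraries, and miR-18a-3p ranged from -0.0044 to 0.20 with time points left out. In IP against input, median-of-ratios rescaling, which shifts the median of all miRNAs, turned miR-212-5p to 0.27, miR-212-3p to 0.17, miR-138-5p to 0.022, miR-411-5p to 0.031, miR-434-5p to 0.019, miR-29a-3p to 0.023, miR-338-5p to 0.058, miR-146a-5p to 0.21 and miR-146b-5p to 0.44.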

Other observations

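Of the tests in this part, the comparison of Ext with Seed constructs and its splits, the use of the planned rescaling as a test of scaling, the fits without libraries that stand apart, the correlation with libraries of other conditions, and, for transduced against non-infected cells, the tests on glial cells and on packaging cells were chosen only after the result was seen.

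Apart from their targets, the neurons with Ext constructs and those with Seed constructs differed in a set of abundant miRNAs. In the 8 Ext libraries miR-99b-5p stood at 277655 ± 58472 (SD, n = 8) normalised reads against 143309 ± 29996 in the 8 Seed libraries (log2 change 0.96), miR-100-5p at 113175 ± 15962 against 61515 ± 15283 (0.91), miR-125b-5p was higher by 0.72 and miR-99a-5p by 0.87. miR-409a-5p (0.98, SE 0.10, limma adjusted p = 9.0e-05), miR-221-5p (1.03) and miR-212-5p (0.96) were higher too, and miR-212-3p is not among the calls. The SE and p rest on the spread within pairs of libraries, which may be technical. The spread among groups of the same construct is not in them. Of the 9 lower ones, miR-132-3p (-0.79) came from the WT target and was at 0.03 with mut groups only, while miR-130a-3p was at -0.39 and miR-185-5p at -0.47, both of which lost the call after median-of-ratios rescaling and without several single libraries.

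In all, 19 of 429 miRNAs were called, 10 higher and 9 lower, with 116 at an unadjusted p under 0.05. For 9 of the 19 the 8 and 8 libraries did not overlap, a count made among miRNAs already called. Chance gives a miRNA this in 0.0155% of cases only if all libraries are independent. They come in groups of 2 whose spread may be technical, so that share is too low. With mut groups only 7 were called, and after median-of-ratios rescaling 17, 15 higher and 2 lower. Leaving out single libraries moved the share of tested miRNAs called from 4.43% to between 2.56% (without replicate 2 of Ext miR-124 WT, among others) and 29.0% (without replicate 2 of Ext miR-132 mut, where 16 were higher and 108 lower). Of 35 splits of the 8 transduced groups into 4 and 4, 1 gave as many calls, the real one, and the highest other gave 11. Since this split was chosen after the difference was seen, the count does not show whether chance can be excluded. The labels do not say whether Ext and Seed cultures were made or sequenced apart, so construct and batch are confounded.

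Other ways of assigning the libraries were counted for each slope of WT over mut and each paired comparison, and not for doxycycline time in mut. For the slope of WT over mut averaged over the series, 3 of 100 assignments, the real one among them, gave as many as the 2 calls (highest other 8). WT and mut were swapped in each series on its own, though the input and IP come from the same cells, so this count does not exclude chance. In total RNA 2 of 32 swaps gave as many as the 129 calls, and the highest other gave 140, so chance cannot be excluded. With 0 real calls any swap gives as many, as 32 of 32 did in the Ago2 input (highest other 2), 32 of 32 in the IP (highest other 4) and 100 of 100 for IP minus input (highest other 7), so the count says nothing there. For IP against input 1 of 100 swaps within pairs, the real one, gave as many as the 410 calls (highest other 293). For input against total RNA 1 of 100, the real one, gave as many as the 357 (highest other 305). A chance assignment of libraries within pairs is argued against in both, if the pairs are independent, which the labels do not show. Input and total RNA are separate experiments, and the swaps do not measure the spread between experiments, so chance is not excluded there.

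Of the 129 slope calls in total RNA 1 remained without the total mut 72 hr library, whose WT partner then drops out of the slope too, 1 without the 8 hr points and 3 after median-of-ratios rescaling. Library scaling stays open and has values on its side. Only those 3 calls remained after rescaling, and before it the median of all slopes was 0.08. A lost call alone does not show a smaller slope, and miR-132-3p lost its call there although its slope became steeper. But miR-132-3p slopes downward, while 115 of the 129 calls were upward, so it does not speak for those. For the total mut 72 hr library, sampling noise from its depth is argued against: its 100 most abundant miRNAs deviated from the series with an SD of 0.83, against a median of 0.17 and a highest of 0.32 for the other total libraries. A library effect shared with other conditions stays open and has a value on its side, since its deviations correlated at 0.59 across 472 miRNAs (which are not independent replicates) with those of Ago2 input WT 4 hr, the highest of 35 libraries, and next at 0.34 with Ago2 IP WT 2 hr. A response to the mut target at 72 hr cannot be told apart from the library itself: the mean correlation with the other 72 hr mut libraries was 0.14, and there is 1 such library per series.

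Transduced neurons differed from non-infected ones in miR-10a and miR-10b, miR-219a-2-3p, miR-17-92 members and all 7 tested arms of miR-322, miR-351, miR-450a, miR-503 and miR-542. Library scaling is argued against as the whole cause, since 28 of the 33 calls remained after median-of-ratios rescaling. Whether fewer glial cells of every kind account for those 7 arms is not decided. Astrocyte-enriched miRNAs had a median of 0.28 (SD of members 0.53), where the 7 arms, chosen after their fall was seen, had a median of -2.71. That list cannot decide it, since its members can move for other reasons. It holds miR-21-5p, which is also on the inflammation-responsive list and rose in transduced cells. The loss of a rarer cell type, as the fall of miR-219a-2-3p might suggest, was not tested. RNA carried over with the virus from packaging cells, a candidate source of miR-10a and miR-10b, cannot be told apart: of 20 miRNAs listed as abundant in a common packaging line, 16 were tested, the 3 others under 100 normalised reads in non-infected cells had a median of 0.34, miR-196a-5p went from 0 to 2.40 and miR-196b-5p from 0 to 0.79, and the abundant members miR-92a-3p and miR-25-3p fell. A response of the neurons to transduction is not tested here and stays open.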
